A study of Bacteroides thetaiotaomicron and Escherichia coli and Escherichia coli
Bacteroides thetaiotaomicron with 24 samples.

How the data were processed

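RNA was counted by MATQ-seq, a random-priming method for very small samples, with rRNA sequences removed at the cDNA stage by a nuclease (DASH). The values are a deposited matrix of raw counts, made by the authors per gene and library for both organisms together, per the labels. The submitters' processing notes credit alignment to Bowtie2 2.3.4.1 and counting to featureCounts, with no version for the latter. The genome build, annotation release, strand setting and handling of reads that map to several genes are not given in the sources used here. The table held 9751 genes (4494 of E. coli and 5257 of B. thetaiotaomicron), of which 363 had no count, and its 24 columns matched the 24 samples with 0 identical columns. Total counts per library ran from 3917 to 974271. No B. thetaiotaomicron identifier matched the reference table, so these genes are given by locus tag, lists defined by product or symbol were left empty for this organism, and the alternative with protein-coding genes only was not run for E. coli.

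Groups were taken from the labels. The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Per library the counts of each organism were then summed, and 8 single-species libraries held the organism that their label does not name. Each organism was therefore fitted over the 16 libraries that hold its counts, a choice made after the counts per library were seen and before any gene was tested; the 16 libraries as labelled are an added alternative. Comparisons that would need a label to be overruled were not made as planned. A pair of comparisons between labelled sets that hold the same organism was added. A further pair that assumed an exchange of names was fitted and then left out, after its counts were seen, since it rests on that assumption. All 24 samples carry 1 entry for the processing, so no batch could be set apart. Correlations of residual profiles did not show that the replicate numbers pair the samples, and they are too few to rule it out.

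Genes of each organism, without rRNA, were filtered with filterByExpr and scaled by TMM within that organism in edgeR 4.0.16 under R 4.3.3. Differences were tested with the edgeR quasi-likelihood F test (2-sided) in a model with a term per group. Benjamini-Hochberg adjusted p-values at or under 0.05 over all genes of a comparison were called. Standard errors are the log2 change divided by the square root of F. CPM values use the TMM-scaled library size of the organism. For E. coli the TMM factors ran from 0.125 in labelled E. coli device replicate 4 to 16.7 in device co-culture replicate 1. The latter had 229 tested E. coli counts, so 1 count weighs far more there, and E. coli means and SDs in CPM carry this unevenness. For a gene with 0 counts in a group, the fold is a lower bound, from the pooled counts per scaled depth against a floor of 3 counts over the group. For 1 to 3 counts, the ratio is given with its exact 95% interval for counting. Gene lists were tested by camera with a preset correlation of 0.01 (limma 3.58.1), adjusted over the lists of 1 organism in 1 comparison, in lists with at least 3 tested members. No list passed with an estimated correlation in any comparison, and those values stand beside the calls. fry was run as a further list test.

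The rule for named genes took, per comparison, the 10 genes that rose and the 10 that fell most among those past 0.05 whose 4 against 4 libraries did not overlap and whose mean in the higher group was at least 50 CPM, up to 4 members per list with the smallest p, and a fixed set of respiration, fermentation, sugar and oxidative stress genes. For B. thetaiotaomicron at most 2 genes per direction are named outside the lists. Of the fixed set cyoA, ldhA, hycE, malK, lamB, ptsG, dcuB, sodA, soxS and BT_3705 did not pass the filter for low counts and were not tested.

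The alternatives planned were poscounts size factors in place of median-of-ratios factors, which the many zeros leave undefined, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a stricter one (at least 10 counts in 4 libraries), a fit of the 8 libraries of a comparison alone, TMMwsp scaling, without libraries under 10000 counts of the organism, rRNA kept, coding genes alone, genes left out above a ratio of 0.1 in libraries of the other organism, a replicate block, and each library left out in turn. Chosen after the data were seen were leaving out ssrA, alone or with the library under 10000 counts, the block without that library, the correlations across genes without it, leaving out the libraries with conflicting labels, the libraries as labelled, and list tests under other scalings, without a filter, without ssrA, without the shallow library and with each library left out. All alternatives of the added comparisons were likewise chosen then. Other splits of the 8 libraries of each comparison (35 with the real one) were fitted in the same way.

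The pipeline was tested on simulated data with the depths of these libraries and 1 spread common to all genes of an organism. In these data 200 of the 1000 most abundant genes were changed, 100 of them 4-fold and 100 of them 16-fold. Differences in spread between genes and outlying libraries were not simulated, so wrong calls may be more frequent in the real data. Recovery is given of all changed genes and, in percent, of those that passed the filter. This simulation was rewritten once, after its first version used scaled depths. For device against liquid in co-culture, E. coli recovered 5 of the genes changed 4-fold (8.33% of the 60 tested) and 48 of those changed 16-fold (76.2% of the 63 tested), with 7 of 60 calls wrong. For co-culture against the libraries labelled E. coli device these were 8 (13.8% of 58) and 53 (82.8% of 64), with 6 of 67 wrong, so wrong calls of E. coli exceeded 5%. For B. thetaiotaomicron, where all changed genes were tested, these were 8 and 80 for device against liquid, with 2 of 90 wrong, and 17 and 82 for liquid co-culture against alone, with 4 of 103 wrong. The share of B. thetaiotaomicron among counts was compared with an exact permutation test (2-sided) in scipy 1.17.1, and intervals of shares are exact Clopper-Pearson. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The interactions of device and partner were left out because each needs a group whose label and content conflict.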

Results

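RNA counts were collected from Escherichia coli and Bacteroides thetaiotaomicron, grown alone or together in liquid or in a microfluidic device with an oxygen gradient, on amylopectin, a branched starch polymer. The 24 libraries formed 6 groups of 4. Per the labels these were B. thetaiotaomicron in liquid (total counts per library 36014 to 886631), B. thetaiotaomicron in the device (25848 to 650090), E. coli in liquid (696016 to 899731), E. coli in the device (62072 to 974271), the co-culture in liquid (804858 to 956168) and the co-culture in the device (3917 to 802209). Over all libraries the median total was 779926 counts. Between 32.5% and 95.7% of the counts (median 70.8%) lay on rRNA genes, which left 654 to 523544 counts per library (median 119378) on other genes. Replicate 1 of the device co-culture was by far the shallowest for both organisms, with 267 E. coli and 387 B. thetaiotaomicron counts outside rRNA. Whether the 4 replicates of a group came from separate cultures is not given in the sources used here, so every p-value measures only the spread between these samples, and counting intervals and floors cover counting error only.

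In 8 of the single-species libraries the counts belonged to the organism that the label does not name. In the 4 libraries labelled B. thetaiotaomicron device, 99.7% to 99.9% of all counts lay on E. coli genes. In each of the 4 libraries labelled E. coli liquid, 99.9% lay on B. thetaiotaomicron genes. The 4 libraries labelled E. coli device held 99.7% to 99.95% E. coli counts and the 4 labelled B. thetaiotaomicron liquid held 99.8% to 99.96% B. thetaiotaomicron counts, as their labels say. Groups are therefore called by their labels, each organism was analysed in the libraries that hold its counts, and every direction drawn with a single-species group rests on its label. The device against liquid comparison of either organism alone, E. coli in co-culture against alone in liquid, B. thetaiotaomicron in co-culture against alone in the device, and the interaction of device and partner could not be tested as labelled.

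**Figure D1:**
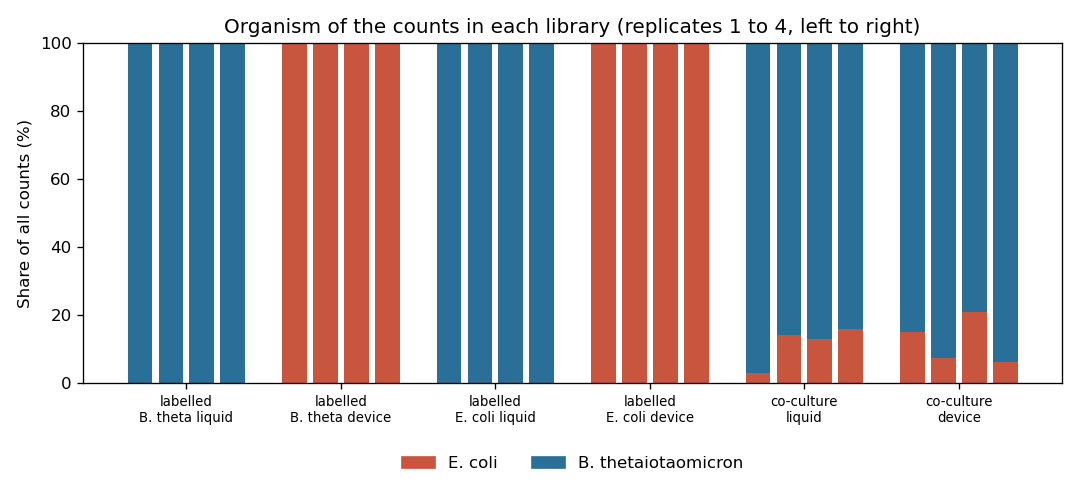
Share of all counts (percent, vertical axis) on E. coli and on B. thetaiotaomicron genes in each of the 24 libraries, 1 bar per library in the 6 labelled groups. The libraries labelled B. thetaiotaomicron device hold 99.7% to 99.9% E. coli counts and those labelled E. coli liquid hold 99.9% B. thetaiotaomicron counts.

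The share of each organism in the co-culture asks how the device shifts the balance of the pair, as far as RNA can show it. Outside rRNA, B. thetaiotaomicron held 69.5% ± 18.0 of the counts in the device (SD, n = 4) and 43.7% ± 18.8 in liquid, a difference of 25.8 percentage points that was within the spread of the replicates (exact permutation test, 2-sided, n = 4 per group, p = 0.0857, smallest possible p 0.0286). The device libraries held 59.2%, 90.2%, 50.6% and 78.1%, and the liquid libraries 71.7%, 33.2%, 37.5% and 32.2%. The widest exact Clopper-Pearson 95% interval was 55.3% to 63.0%, in device replicate 1. As background, B. thetaiotaomicron held 0.0211% to 0.0376% in the libraries labelled E. coli device. ssrA, the tmRNA that frees stalled ribosomes, took 72.6% ± 10.7 of the E. coli counts outside rRNA in the device and 79.2% ± 17.1 in liquid (SD, n = 4). Without ssrA, an alternative chosen after the data were seen, B. thetaiotaomicron held 87.5% ± 8.80 in the device and 81.9% ± 1.96 in liquid, a difference of 5.65 points (exact permutation test, 2-sided, p = 0.371). With rRNA kept the difference turned to -0.849 points (87.6% ± 6.93 in the device, 88.4% ± 5.77 in liquid; exact permutation test, 2-sided, p = 0.886).

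In the co-culture, E. coli in the device was compared with E. coli in liquid, which asks how it adjusts to the gradient beside its partner. As groups, by a test with a preset correlation, genes for ribosomal proteins, for glucose transport and glycolysis, for cold shock and for mixed-acid fermentation, the route to formate, acetate and ethanol without oxygen, rose in the device, and genes for the use of other sugars under CRP, the cAMP receptor protein, fell. None of the 5 calls held with an estimated correlation (adjusted p = 0.255 to 0.467 with an estimated correlation). Per gene, ribosomal protein genes held 0.241, 1.97, 0.343 and 0.861 times the counts of 91 genes taken to be silent in such media in the liquid libraries. That these genes, called silent genes below, were silent here was assumed and not tested. In the device they held 0, 3.11, 11.3 and 14.0 times, where the 0 rests on 0 ribosomal and 1 silent count in replicate 1. The ratio uses the ribosomal protein genes themselves, so it restates that call in part. Whether it reflects RNA quality was not tested. Of 520 genes tested, 3 rose and 3 fell. fabG, for the ketoacyl reductase of fatty acid synthesis, was higher in each of the 4 device libraries than in any liquid library, at 751 ± 770 CPM (counts scaled to a common library size; SD, n = 4) against 20.9 ± 41.8. Its 62 device counts (1 of them in device replicate 1) against 3 liquid counts, all in 1 library, gave a ratio of 30.2 (95% counting interval 9.86 to 150.4, adjusted p = 0.0186). The 3 genes that fell had no device count. ychH, for a membrane protein linked to stress, was at least 18.3-fold lower against a floor of 3 counts over the group (80 liquid counts, 597 ± 330 CPM, adjusted p = 0.0186). amtB, the ammonium transporter, was at least 6.84-fold lower (30 liquid counts, adjusted p = 0.0420), and hrpB, for a predicted helicase, at least 7.07-fold lower (31 liquid counts, adjusted p = 0.0420); each of the 3 had counts in all 4 liquid libraries. Outside the naming rule, and chosen after their values were seen, miaA, a tRNA-modifying enzyme, had 28 device against 2 liquid counts (ratio 20.5, interval 5.16 to 177, adjusted p = 0.0496), and ileS, the isoleucyl-tRNA synthetase, rose by 3.45 ± 0.91 log2 units (SE; 559.9 ± 378 against 51.6 ± 60.0 CPM, SD, n = 4, adjusted p = 0.0496).

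The filter for low counts kept only part of each E. coli list. It kept 9 of 54 ribosomal protein genes, 6 of 23 for glycolysis, 11 of 31 for mixed-acid fermentation, 3 of 11 for cold shock and 8 of 53 for other sugars. A gene can pass it through a group where it is high, so a shared direction may come in part from the filter. The 9 ribosomal protein genes tested all had a positive change (adjusted p = 0.00102 for the list by camera, adjusted p = 0.467 with an estimated correlation). None passed over all genes and 6 rose when adjusted over the list alone, with rplF at a log2 change of 3.51 ± 1.04 (SE; adjusted p = 0.1002) and rplE at 3.65. The 6 glycolysis genes tested were all positive (adjusted p = 0.00173; adjusted p = 0.447 with an estimated correlation), 0 over all genes and 2 adjusted over the list alone, with pgk at 3.68 ± 1.13 (adjusted p = 0.102) and gapA at 2.16. Of 11 mixed-acid fermentation genes 10 were positive (adjusted p = 0.0290; adjusted p = 0.467 with an estimated correlation) and 0 passed over all genes or adjusted over the list alone. pflB, pyruvate formate-lyase, stood at 10877 ± 9423 CPM in the device and 1595 ± 1622 in liquid (SD, n = 4; log2 2.78 ± 1.20, SE; adjusted p = 0.192, range 0.0499 to 0.633 over the alternatives) and adhE at a log2 change of 1.44 (adjusted p = 0.417). The 3 cold shock genes, cspA (3.05), deaD (3.01) and pnp (2.56), rose as a list (adjusted p = 0.0173; adjusted p = 0.447 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone. Of 8 genes for other sugars 7 were negative (adjusted p = 0.00526; adjusted p = 0.255 with an estimated correlation), 0 over all genes and 3 lower adjusted over the list alone, among them gatY and gatZ for galactitol use at -3.61 ± 1.14 and -3.28 ± 1.04 (SE). Genes of oxygen respiration showed no detectable change, with cydA of the high-affinity oxidase at -0.20 (adjusted p = 0.956) and sdhA of succinate dehydrogenase at 0.22 (adjusted p = 0.956). frdA, fumarate reductase, was at -0.23 (adjusted p = 0.938), and each of these 3 changed sign under some other settings. Their counts were few, 25 in the device and 30 in liquid for cydA, 7 and 7 for sdhA and 18 and 24 for frdA. A change could thus have been missed, and these values do not show that respiration was stable. The mixed-acid call ended without liquid replicate 1 (adjusted p = 0.264), liquid replicate 3 (0.152) or device replicate 3 (0.149), and the 3 cold shock genes were too few to test without device replicate 3. The count of 6 genes became 0 without device replicate 3 or 4, 3 without device replicate 2, 15 without device replicate 1 and 51 without liquid replicate 2. Its split changed from 3 higher and 3 lower to 1 higher and 3 lower under either other scaling, and fabG kept its call in 3, amtB in 4 and hrpB in 3, ychH in 6, miaA in 2 and ileS in 1 of the 8 fits that left out a library. Over the other settings the count ran from 2 with a replicate block to 25 with DESeq2, and with no filter 3 passed and fabG, amtB, hrpB, miaA and ileS lost their calls.

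**Figure D2:**
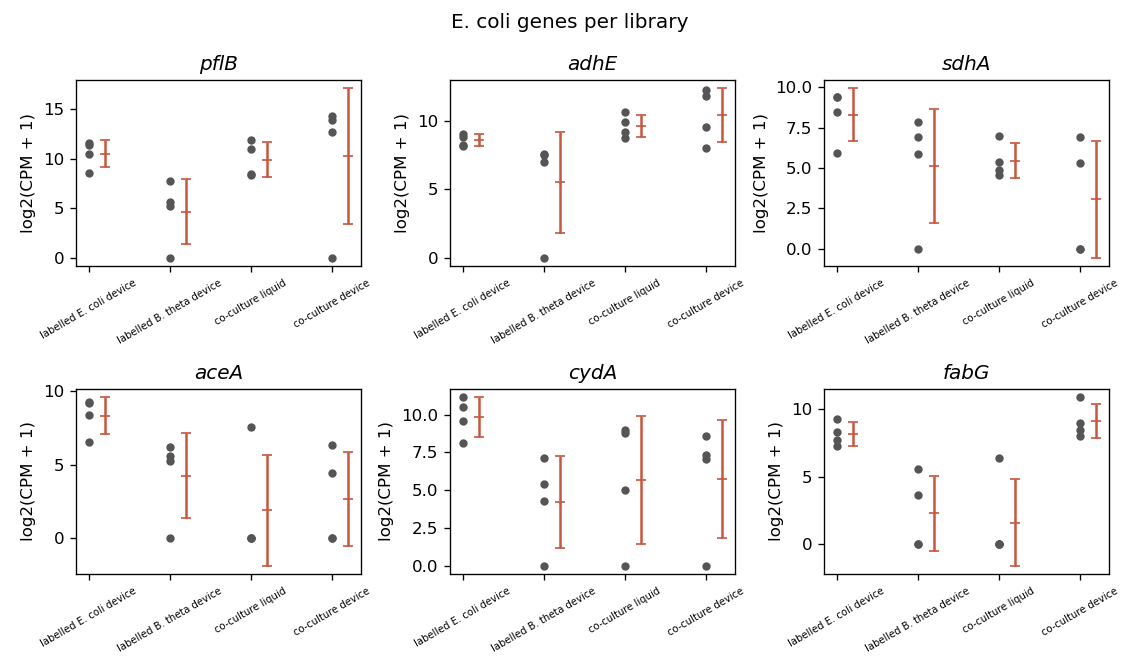
Expression of 6 E. coli genes (pflB, adhE, sdhA, aceA, cydA and fabG) as log2(CPM + 1) on the vertical axis, in the 4 groups whose libraries hold E. coli counts, named by their labels. Points are the 4 libraries of a group (some at 0 overlap), and the red dash and bars are the mean and SD of log2(CPM + 1); fabG lies higher in all 4 device co-cultures than in any liquid co-culture, while pflB did not pass the test between them.

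E. coli in the device co-culture was compared with the libraries labelled E. coli device, which asks what the partner changes in the gradient. Read by its label, and by the preset correlation, genes of aerobic respiration and the TCA cycle, of acetate, C4-dicarboxylate and propionate use and of other CRP-dependent sugars fell as groups in E. coli beside B. thetaiotaomicron, and genes for heat shock and proteolysis, for mixed-acid fermentation, for glycolysis and for cold shock rose. None of the 7 calls held with an estimated correlation (adjusted p = 0.0806 to 0.317 with an estimated correlation). Ribosomal protein genes held 0.398, 4.62, 2.06 and 10.2 times the counts per gene of the silent genes in the libraries labelled E. coli device, beside 0, 3.11, 11.3 and 14.0 in the device co-culture. No single gene of 520 passed (0 by edgeR, with 75 at an unadjusted p under 0.05; 33 by DESeq2 and 2 by limma-voom), so all calls in this comparison are of lists.

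Here too the filter for low counts kept only part of each list, with 13 of 38 respiration and TCA genes. It kept 9 of 22 for acetate, C4-dicarboxylate and propionate use and 13 of 22 for heat shock. All 13 respiration and TCA genes tested were negative (adjusted p = 2.01e-06 for the list, adjusted p = 0.0806 with an estimated correlation). Of these, 0 passed over all genes and 8 were lower adjusted over the list alone. sucA, of 2-oxoglutarate dehydrogenase, stood at 83.1 ± 125 CPM in the co-culture and 2579 ± 1592 alone (SD, n = 4; log2 -4.51 ± 1.20, SE; adjusted p = 0.0606), and cyoB, of the low-affinity oxidase, at 84.5 ± 77.3 and 1042 ± 609 CPM (adjusted p = 0.0659). icd, isocitrate dehydrogenase, had 2 counts in the co-culture and 246 alone, a ratio of 22.9 (95% counting interval 6.27 to 190.1), and nuoL, of NADH dehydrogenase, had 1 and 197, a ratio of 36.7 (6.50 to 1455). Of 9 genes for acetate, C4-dicarboxylate and propionate use 8 were negative (adjusted p = 0.00513; adjusted p = 0.134 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone, with actP, the acetate permease, at -2.77 and aceA, isocitrate lyase, at 3 counts against 203 (ratio 12.6, interval 4.25 to 61.6, adjusted p = 0.101). Of 13 heat shock genes 12 were positive (adjusted p = 3.79e-07; adjusted p = 0.134 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone, among them the small chaperone gene ibpB at 752 ± 759 against 50.01 ± 48.0 CPM (SD, n = 4; log2 3.95 ± 1.23, SE; adjusted p = 0.0748) and the disaggregase gene clpB at 3.05 ± 1.03. Of 11 mixed-acid genes 9 were positive (adjusted p = 0.00530; adjusted p = 0.317 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone, with adhE at 2.61 ± 0.96 (adjusted p = 0.146) and pflB at 2.51 ± 1.19 (adjusted p = 0.302). Of 6 glycolysis genes 5 were positive (adjusted p = 0.00842; adjusted p = 0.292 with an estimated correlation), and the 3 cold shock genes were all positive (adjusted p = 0.00530; adjusted p = 0.231 with an estimated correlation). Without device co-culture replicate 3 the cold shock genes were too few to test. Of 8 genes for other sugars 7 were negative (adjusted p = 0.0325; adjusted p = 0.226 with an estimated correlation), 0 over all genes and 2 adjusted over the list alone, with gatY at -4.55 ± 1.18 and gatZ at -4.26 ± 1.06 (SE). The median log2 change of all genes was -0.41, against which these changes stand. The oxidase gene cyoA, with 276 counts alone and 1 in the co-culture, did not pass the filter for low counts and was not tested. Without ssrA, an alternative chosen after the data were seen, the calls of glycolysis (adjusted p = 0.0556), acetate and C4-dicarboxylate use (0.0556) and other sugars (0.0539) ended with their directions kept, and 14 genes passed. With poscounts scaling 17 genes passed (1 higher, 16 lower), and 21 or 5 passed without replicate 1 or 4 of the libraries labelled E. coli device.

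The libraries labelled E. coli device were compared with those labelled B. thetaiotaomicron device, since both hold E. coli, a comparison added after the content of the libraries was seen. In the libraries labelled E. coli device, 73 of 520 genes were higher and none lower (edgeR, with 120 at an unadjusted p under 0.05; DESeq2 gave 76 higher and 2 lower, limma-voom 77 and 1). The porin genes ompF and ompC rose by 6.46 ± 1.32 and 6.06 ± 1.20 log2 units (SE), from 31.7 ± 37.2 to 2386 ± 1781 CPM and from 16.6 ± 16.8 to 1293 ± 664 CPM (SD, n = 4; adjusted p = 0.00215 for each). rpsG, a ribosomal protein gene, was at least 53.8-fold higher (227 counts against 0, floor of 3 counts over the group). gcvB, a small RNA that represses amino acid transport, had 469 counts against 2 (ratio 167, interval 45.9 to 1382), rpsL 221 against 1 (ratio 157, interval 27.9 to 6239) and bamD, of the outer membrane assembly machine, 208 against 3 (ratio 49.3, interval 16.6 to 241). purA, of AMP synthesis, and aceB, malate synthase, both rose by 5.59 (adjusted p = 0.00215 and 0.00288), and fliC, flagellin, by 5.21 ± 1.11 (adjusted p = 0.00215). Of the groups, 8 of 9 ribosomal protein genes rose, and 9 adjusted over the list alone (adjusted p = 1.40e-06; adjusted p = 0.458 with an estimated correlation), as did 5 of 6 glycolysis genes, and 5 adjusted over the list alone (adjusted p = 0.00177; adjusted p = 0.458 with an estimated correlation). Of 13 respiration and TCA genes 2 rose, and 4 adjusted over the list alone (adjusted p = 0.00962, adjusted p = 0.458 with an estimated correlation). These lists hold 54, 23 and 38 genes, and members may have passed the filter for low counts through the group where they are high. cydA rose by 4.66 ± 1.14 (adjusted p = 0.00436) and pflB by 4.58 ± 1.32 (adjusted p = 0.0137). Ribosomal protein genes held 0.0643 to 0.251 times the counts per gene of the silent genes in the 4 libraries labelled B. thetaiotaomicron device, against 0.398 to 10.2 in those labelled E. coli device. The respiration and TCA call ended without ssrA (adjusted p = 0.229) and without replicate 2 (0.134) or 3 (0.164) of the libraries labelled E. coli device, the glycolysis call ended without ssrA (0.0555), pflB lost its call without replicate 4 of those labelled B. thetaiotaomicron device (adjusted p = 0.0618, range 0.00349 to 0.0618 with each library left out) and with a replicate block, with no filter 131 and with the 8 libraries fitted alone 160 genes passed, and without replicate 1 of those labelled E. coli device 113 genes passed.

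B. thetaiotaomicron in the co-culture was compared between device and liquid, which asks how the gradient changes the polysaccharide-degrading partner. Its genes are given by locus tag, since names and products are not given in the sources used here. As groups, the loci for arabinan, galactan and rhamnogalacturonan, the pectic polysaccharides, the yeast mannan loci and the capsule locus CPS8 fell in the device by the preset correlation, and none of the 3 did with an estimated one (adjusted p = 0.503 with an estimated correlation for each). No single gene of 2353 passed (0 by edgeR, with 495 at an unadjusted p under 0.05; 85 by DESeq2 and 0 by limma-voom). Of 36 genes of the pectic loci 35 were negative (adjusted p = 1.55e-06; adjusted p = 0.503 with an estimated correlation) and 0 passed over all genes or adjusted over the list alone, with BT_0367 at 48.6 ± 75.4 CPM in the device and 618 ± 206 in liquid (SD, n = 4; log2 -3.14 ± 1.01, SE; adjusted p = 0.178). All 10 CPS8 genes were negative (adjusted p = 7.24e-05; adjusted p = 0.503 with an estimated correlation), 0 over all genes and 7 lower adjusted over the list alone, with BT_0061 at 867 ± 690 against 3771 ± 1271 CPM (log2 -2.03 ± 0.85, SE) and BT_0066 at -2.61 ± 1.03. Of 19 mannan genes 16 were negative (adjusted p = 0.0410; adjusted p = 0.503 with an estimated correlation), 0 passed over all genes, and the call ended without liquid replicate 2 (adjusted p = 0.0595) or device replicate 4 (0.0682). The starch utilisation locus (Sus), whose products bind and cleave amylopectin, did not pass (adjusted p = 0.263); 6 of its 7 genes were positive, with BT_3701 at 1.88 ± 0.85 (SE; adjusted p = 0.203) and BT_3704 at 2.22. Without liquid replicate 2, 91 genes passed, with no filter 15, and with the 8 libraries fitted alone 1.

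In liquid, B. thetaiotaomicron in the co-culture was compared with the libraries labelled B. thetaiotaomicron liquid, which asks what E. coli changes in its partner. The Sus locus fell beside E. coli, while the pectic loci and CPS8 rose, by the preset correlation and not with an estimated one (adjusted p = 0.443 with an estimated correlation for each). Single genes passed in both directions, 5 higher and 19 lower of 2353. All 7 Sus genes tested were negative (adjusted p = 7.27e-04; adjusted p = 0.443 with an estimated correlation), and 1 passed over all genes and 3 adjusted over the list alone. BT_3699 stood at 207 ± 127 CPM in the co-culture and 1730.3 ± 1117 alone (SD, n = 4), a change of -3.07 ± 0.81 log2 units (SE; adjusted p = 0.0438), and BT_3701 at -2.54 ± 0.87 (adjusted p = 0.151). Of 36 genes of the pectic loci 29 were positive (adjusted p = 1.81e-04; adjusted p = 0.443 with an estimated correlation) and 0 passed over all genes or adjusted over the list alone, with BT_0363 at 1.98 ± 0.82 (SE) and BT_4182 at 1.68. Of 10 CPS8 genes 9 were positive (adjusted p = 0.0233; adjusted p = 0.443 with an estimated correlation), with BT_0060 at 1.40 ± 0.75. Outside the lists, BT_0210 was at least 21.3-fold higher in the co-culture (37 counts against 0, floor of 3 counts over the group, adjusted p = 0.0125) and BT_2190 at least 13.2-fold higher (23 against 0, adjusted p = 0.0346). BT_2738 had 1 count against 76 (ratio 44.1, interval 7.67 to 1763, adjusted p = 0.0110) and the tRNA gene BT_t67 had 3 against 203 (ratio 39.2, interval 13.2 to 192, adjusted p = 0.00717). The CPS8 call ended without replicate 1 (adjusted p = 0.164) or 2 (0.286) of the libraries labelled B. thetaiotaomicron liquid or replicate 1 (0.102), 2 (0.0523), 3 (0.181) or 4 (0.113) of the liquid co-culture, BT_3699 lost its call without replicate 3 of the former or 3 or 4 of the latter (range 0.000407 to 0.0851), and BT_2190 without replicate 1 or 3 of the former or 4 of the latter (highest adjusted p = 0.0652). The count of 24 genes became 435 without replicate 4 of the libraries labelled B. thetaiotaomicron liquid, and 74, 11 and 15 without replicates 2, 3 and 4 of the liquid co-culture. It was 0 when the 8 libraries were fitted alone, 10 with a replicate block, 10 with limma-voom, 49 with rRNA kept, 65 with no filter and 115 with DESeq2. BT_3699 lost its call with limma-voom, with the block and with the 8 libraries alone, BT_2190 with limma-voom and the block, and BT_t67 with the 8 libraries alone, where BT_0210, BT_2190 and BT_2738 were too rare to be tested. Among settings chosen after the data were seen, the count was 5 without the libraries with conflicting labels (0 higher, 5 lower), 3 with the libraries as labelled (0 higher, 3 lower) and 10 with the block without the shallow library, and BT_3699 lost its call in each. BT_0210 and BT_2190 were too rare to be tested in the former 2 settings and lost their calls in the last.

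The libraries labelled E. coli liquid were compared with those labelled B. thetaiotaomicron liquid, since both hold B. thetaiotaomicron, again a comparison added after the content of the libraries was seen. In those labelled E. coli liquid, 28 of 2353 genes were higher and 33 lower, a balance that turned to more higher than lower under most other settings (such as 84 and 28 with no filter, 45 and 19 with the 8 libraries fitted alone, 68 and 52 with DESeq2, 41 and 27 with limma-voom and 28 and 25 with TMMwsp). The Sus locus and CPS8 fell as groups by the preset correlation and not with an estimated one (adjusted p = 0.387 and 0.557 with an estimated correlation). All 7 Sus genes were negative (adjusted p = 1.84e-04; adjusted p = 0.387 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone, with BT_3704 at -3.27 ± 1.08 (SE; adjusted p = 0.114). All 10 CPS8 genes were negative (adjusted p = 0.00113; adjusted p = 0.557 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. BT_4634 was at least 21.1-fold higher (240 counts against 0, adjusted p = 0.00583) and BT_3159 at least 16.8-fold higher (191 against 0, adjusted p = 0.0160). The noncoding RNA gene BTnc017 fell by 5.85 ± 1.14 and the tRNA gene BT_t21 fell by 5.84 ± 1.23 log2 units (SE; adjusted p = 0.00410 and 0.00583). Of list members, BT_4150 of the pectic loci fell by 3.12 ± 0.83 (adjusted p = 0.0290), BT_1357 of CPS4 fell by 3.15 ± 0.85 (adjusted p = 0.0301) and BT_1724 of CPS6 fell by 3.69 ± 0.92 (adjusted p = 0.0187). The other 3 CPS6 genes tested were positive and rose when adjusted over the list alone, and the pectic, CPS4 and CPS6 lists did not pass (adjusted p = 0.360, 0.306 and 0.375). The CPS8 call ended without replicate 4 of the libraries labelled B. thetaiotaomicron liquid (adjusted p = 0.105), BT_t21 lost its call without replicate 1 of those labelled E. coli liquid (adjusted p = 0.0530), BT_3159 without that library or replicate 3 of those labelled B. thetaiotaomicron liquid (highest 0.0534), and BT_4150, BT_1357 and BT_1724 kept theirs in 1, 2 and 2 of 8 fits. Without replicates 2, 3 and 4 of the libraries labelled B. thetaiotaomicron liquid 33, 28 and 168 genes passed, and without replicates 1, 3 and 4 of those labelled E. coli liquid 19, 23 and 23. DESeq2 gave 120, no filter 112 and the block without the shallow library 32, and BT_4150 and BT_1357 lost their calls with no filter and with a replicate block.

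The effect of the device in co-culture was set beside the difference between the labelled sets that hold the same organism, which share no library with it. Across 520 E. coli genes, the change from liquid to device in co-culture and the change from libraries labelled B. thetaiotaomicron device to those labelled E. coli device had a Pearson correlation of 0.488 (Spearman 0.448). Across 2353 B. thetaiotaomicron genes, the change from liquid to device in co-culture and that from labelled B. thetaiotaomicron liquid to labelled E. coli liquid had 0.315 (0.371). These are correlations across genes, which are not independent replicates, and no p-value was computed. Without the shallow library, an alternative chosen after the data were seen, they were 0.421 and 0.222.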

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

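In this part the tests of an exchange of names and of a wrong organism in the label (its B. thetaiotaomicron part) were fixed before their results were seen, and its E. coli part and the tests of spilled reads, background sequence, ssrA, the place of B. thetaiotaomicron liquid replicate 4 and the splits were chosen after.

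The 4 libraries labelled B. thetaiotaomicron device hold at least 99.7116% E. coli counts and the 4 labelled E. coli liquid hold at least 99.9135% B. thetaiotaomicron counts. No planned comparison that was made contrasted these sets, but they entered the filter, scaling and spread of its fit. Reads spilled from the single-species libraries held here would carry their source's profile. These sets differed from those that hold the same organism in 61 B. thetaiotaomicron and 73 E. coli genes, against at most 17 and 14 in any other split. This argues against such spill and does not exclude it, since a profile altered by background sequence would also differ. Sources outside these libraries were not tested. An exchange of names between both sets would let each organism's changes between its labelled sets follow those from liquid to device in co-culture; the lower of both correlations across genes was 0.315, above the bound of 0.1, but the Sus genes went opposite ways (6 of 7 positive in co-culture, not past the test, and all 7 negative between the labelled sets), and in E. coli the median ratio of ribosomal to silent genes was higher on the same side in both, so an exchange may stand and is not shown. A label wrong in organism only would make each pair of sets that hold 1 organism 2 sets from 1 condition: 2.59% of B. thetaiotaomicron genes differed, under the bound of 5% written for it, but the real grouping called 61 genes against at most 17 in any other split (a condition added after these values were seen), and 14.0% of E. coli genes differed, over that bound, with 73 called against at most 14. These values count against this reading, which stays open because background sequence in 1 E. coli set may also give such calls and sets from 1 condition could differ by preparation; a difference in growth was not tested.

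All 73 E. coli genes called between the 2 sets of single-species device labels were higher in the libraries labelled E. coli device. No other split of these 8 libraries called more than 14, so 1 of 35 splits (the real one) was as large. That is the smallest share that 35 splits can give. It argues against chance and does not exclude it, since the splits were chosen after the data were seen and run on several comparisons. The share of counts on ssrA is excluded as the whole cause, since 57 genes passed without it. Background sequence in place of transcripts in the libraries labelled B. thetaiotaomicron device may account for it. There, ribosomal protein genes held at most 0.251 times the counts per gene of 91 genes assumed to be silent. If some of the 91 were expressed, the ratio would not measure background sequence. Ribosomal protein genes are also among the 73 genes called, so this ratio restates the calls in part and cannot decide. Ribosomal protein genes are short, which lowers this ratio, gene lengths were not used here, and the ratio was also below 1 in replicate 1 of the libraries labelled E. coli device and in replicates 1, 3 and 4 of the liquid co-culture. A biological difference between the labelled sets stays open, untested.

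Replicate 4 of the libraries labelled B. thetaiotaomicron liquid lay nearer to the liquid co-culture, with a mean correlation of log2 profiles across 1313 genes of 0.374 to it and -0.195 to its own group (0.302, 0.338 and 0.379 for the others). An exchange of names with a liquid co-culture library is excluded, since its counts outside rRNA were 0.0176% E. coli. Background sequence that flattens the profile could account for it, since 2294 genes were detected at 10000 counts against 1727, 1984 and 2244 in the other 3, but the gap to the nearest is small and these cannot be told apart from spread between libraries on 4 values. No biological explanation was tested.

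For E. coli device against liquid in co-culture chance cannot be excluded: 6 of 35 splits called as many genes as the real 6, and the highest other called 44. For E. coli co-culture device against labelled E. coli device all 35 called at least the real 0, the highest other 1, which excludes nothing. For B. thetaiotaomicron device against liquid the real split called 0, so that all 35 called as many by construction, which again excludes nothing, and the highest other called 105. For liquid co-culture against labelled B. thetaiotaomicron liquid 4 of 35 called as many as the real 24 and the highest other called 450, so chance cannot be excluded. For the sets labelled E. coli liquid and B. thetaiotaomicron liquid 1 of 35 splits (the real one) called as many as the real 61, and the highest other called 17. This argues against chance and does not exclude it, for the reasons given above for the labelled device sets. The split with 450 calls exchanges replicate 4 of the libraries labelled B. thetaiotaomicron liquid with replicate 2 of the liquid co-culture. Those with 105 and 44 exchange liquid with device co-culture libraries (liquid replicate 2 and device replicate 1). That device library is the shallow one, with 387 B. thetaiotaomicron and 267 E. coli counts outside rRNA. A structure of the samples beyond their groups was not tested.

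Further libraries stood far from the other 3 of their group, in 13 of 66 groups tested here. For normally distributed values, chance gives this in about 1 in 20 groups. The values were not transformed, and several measures came from the same libraries, so 13 of 66 cannot be weighed against that rate. In 5 of the 13 a gene had 3 libraries at 0, which meets the rule by construction, so that rate does not apply to them; the groups screened for single genes were narrowed, after the results were seen, to those of the comparison that names the gene. Total counts were 696016 in labelled E. coli liquid replicate 2 (others 887987 to 899731), 62072 in labelled E. coli device replicate 1 (others 916924 to 974271) and 3917 in device co-culture replicate 1 (others 679730 to 802209). Liquid co-culture replicate 1 had 95.7% rRNA counts (others 86.6% to 87.5%), 71.7% B. thetaiotaomicron outside rRNA (others 32.2% to 37.5%) and 53.6% ssrA among E. coli counts outside rRNA (others 86.2% to 89.0%). In single liquid co-culture libraries BT_2738 stood at 31.6 CPM, fabG at 83.6 CPM and miaA at 81.1 CPM, with the others at 0. In a single device co-culture library fabG stood at 1897 CPM (others 262 to 489). rpmI stood at 46.1 CPM and rpsL at 5.89 CPM in single libraries labelled B. thetaiotaomicron device (others 0), and rpmI at 1799 CPM in a library labelled E. coli device (others 197 to 464).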

How the results depend on the processing

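Chosen after the data were seen were leaving out ssrA (alone or with the shallow library, device co-culture replicate 1), the block without that library, leaving out the libraries with conflicting labels, the libraries as labelled, the list tests under other scalings, filters or libraries, and all settings of both comparisons between labelled sets of 1 organism; the others were planned. No called gene reversed its direction under any setting in which it was tested, but some called genes were not tested under every setting. All 23 list calls of the 6 comparisons kept direction and call under poscounts and TMMwsp scaling. The cause of each change below was not tested, except that fits of fewer libraries or genes differ by construction. The genes tested differed as well, so these counts are not 1 set of calls that grew or shrank. For E. coli device against liquid, 520 genes were tested in the main fit. A stricter filter tested 57 (1 of the main calls kept), the libraries as labelled 65 (0 kept) and the fit without ssrA 219 (4 kept). The 8 libraries alone tested 60 and called 4 (1 kept). For E. coli co-culture device against labelled E. coli device, these settings tested 396, 65, 219 and 90. E. coli device against liquid in co-culture (6 genes) gave 25 genes with DESeq2, 12 with limma-voom, 3 with no filter, 13 with a stricter filter, 11 with rRNA kept, 15 without the shallow library, 2 with a replicate block (pairing the numbers), 13 without ssrA, 24 without ssrA and the shallow library, 2 without the libraries with conflicting labels and 12 with the libraries as labelled. E. coli co-culture device against labelled E. coli device (0 genes) gave 17 with poscounts, 33 with DESeq2, 2 with limma-voom, 12 with no filter, 17 with a stricter filter, 17 with the 8 libraries alone, 14 without ssrA, 9 with the block without the shallow library and 13 as labelled. Labelled E. coli device against labelled B. thetaiotaomicron device (73) gave 131 with no filter and 160 with the 8 libraries alone. B. thetaiotaomicron device against liquid (0) gave 85 with DESeq2, 15 with no filter and 1 with the 8 libraries alone. Liquid co-culture against labelled B. thetaiotaomicron liquid (24) gave 115 with DESeq2, 10 with limma-voom, 65 with no filter, 0 with the 8 libraries alone, 49 with rRNA kept, 10 with the block, 10 with the block without the shallow library, 5 without the libraries with conflicting labels and 3 as labelled. Labelled E. coli liquid against labelled B. thetaiotaomicron liquid (61) gave 120 with DESeq2, 112 with no filter and 32 with the block without the shallow library. Camera called 18 lists in the 4 planned comparisons, of which 0 passed with an estimated correlation; fry called 6 lists, among them oxidative stress and amino acid biosynthesis, which camera did not call. With each library left out, the counts ran, in the order above, from 0 to 51, 0 to 21, 61 to 113, 0 to 91, 11 to 435 and 19 to 168, and the list calls from 15 to 22. The difference in B. thetaiotaomicron share ran from 18.9 to 35.2 points; with 3 against 4 libraries the smallest exact p is 0.0571, reached without liquid replicate 1, so these fits could not pass. In the same order, the median log2 change of all genes was -0.12, -0.41, 0.06, -0.16, -0.01 and -0.20 with TMM, -0.30, -0.56, -0.09, 0.11, -0.06 and -0.08 with poscounts, and -0.23, -0.47, -0.09, 0.20, -0.15 and -0.02 with TMMwsp. Among fixed genes that did not pass, cydA, aceA, sdhA, frdA, appC and acs changed sign under some settings between device and liquid. At the depths of these libraries and 1 spread common to all genes, 5 to 17 of 100 genes changed 4-fold were recovered on simulated data. Depth alone was not varied. Not run were coding genes alone for E. coli and for the share of the organisms, since gene classes are not given, median-of-ratios factors, and the planned comparisons that the labels do not allow.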

Other observations

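The tests without device co-culture replicate 1 in this part were chosen after the data were seen. Further gene groups passed without that library and not with it, where more E. coli genes could also be tested (944 against 520). Without it, the lists for anaerobic respiration (24 genes tested against 16, adjusted p = 0.0453 by camera), general stress under RpoS (0.0258) and acid resistance (0.0440) fell between device and liquid in co-culture. These calls ended with an estimated correlation (adjusted p = 0.317, 0.196 and 0.254). In the same setting ribosomal protein genes (24 tested) rose in the device co-culture against the libraries labelled E. coli device (adjusted p = 3.28e-08), cold shock genes rose in the libraries labelled E. coli device against those labelled B. thetaiotaomicron device (0.00755), and in B. thetaiotaomicron the mannan loci rose in the liquid co-culture against labelled B. thetaiotaomicron liquid (0.0135) while the CPS8 call there ended (0.0904). With an estimated correlation the adjusted p of these 3 gains was 0.226, 0.449 and 0.344.

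Of the other fixed lists of E. coli, those for high-affinity oxidases, anaerobic respiration, maltose, oxidative stress, general stress, acid resistance, SOS, flagella and chemotaxis, curli and fimbriae, iron, amino acid synthesis, sulfate, nitrogen and glycogen passed by camera in none of the 3 comparisons, with adjusted p from 0.130 to 0.939 between device and liquid, 0.310 to 0.989 between co-culture and labelled E. coli device and 0.159 to 0.997 between the labelled sets, ranges that cover every list without a call. By fry, which asks only whether a list's genes move 1 way, oxidative stress (3 genes, all negative) and amino acid synthesis (16 of 22 negative) passed between co-culture and labelled E. coli device (adjusted p = 0.0478 each), and high-affinity oxidases (3 genes, all positive) between the labelled sets (0.0218). Between device and liquid, hyaB, of a hydrogenase, had a log2 change of -3.10 ± 0.96 (SE; adjusted p = 0.102), katG, a catalase, -2.35 (adjusted p = 0.167) and ahpC, of alkyl hydroperoxide reductase, 2.90 (adjusted p = 0.161). Of B. thetaiotaomicron, the levan, heparin and chondroitin, CPS1, CPS2, CPS3, CPS4 and CPS6 lists passed by camera in none, with adjusted p from 0.0787 to 0.929, 0.0571 to 0.872 and 0.191 to 0.511 in the 3 comparisons. The mannan loci, which passed between device and liquid, had 0.0517 and 0.558 in the other 2. By fry CPS1 passed between the labelled sets (2 of 3 genes positive, adjusted p = 0.0479). Lists for envelope stress and phosphate limitation in E. coli and CPS5 and CPS7 in B. thetaiotaomicron had under 3 tested genes. The list median, mean and test differed in sign in 1, 5 and 6 E. coli lists and 2, 1 and 1 B. thetaiotaomicron lists of these comparisons, none of which passed.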
